A study of Saccharomyces cerevisiae with 26 samples.

How the data were processed

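RNA of 26 samples in 9 groups was hybridized to Affymetrix yeast arrays that carry 10928 probe sets. The deposited value is a ratio, obtained per the submitters' processing notes after summarising with RMA (version not given in the sources used here). The values are linear ratios from 0.0102 to 159. Each probe set's median over the 26 arrays lies between 0.9905 and 1.047 and each array's median between 0.998 and 1, so the deposited ratio sets a probe set's signal against its own median over the 26 arrays and the absolute signal level is lost. Arrays give no counts, and their number limits the precision.

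Log2 of the deposited ratios was taken. Of the probe sets, 5498 were tied by the platform annotation to exactly 1 gene of Saccharomyces cerevisiae and stood for 5449 genes. For 47 genes with more than 1 such probe set the one with the highest mean ratio was used, since brightness is not in the values. Another 4 genes had missing values and were left out, which left 5445. Probe sets not listed in the annotation (3683, of which 166 were Affymetrix controls), 1 with several symbols and 1746 of another organism were not tested. Some probe sets, among them those of PAU2, PAU3, PAU5, PAU24, HXT7, RPL41A and YLR154C-H, carry an identifier suffix (x_at or s_at) by which Affymetrix marks probes that can bind several transcripts, so these values may include signal of near-identical genes; those of TIR1, TIR3, TIR4, FLO1 and HXT1 do not. Genes are given without coordinates because no genome build is stated for the values.

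A model of 9 group means was fitted to the 26 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 21.02 residual and prior degrees of freedom. The log-phase, stationary-phase, chemostat and day 0 groups hold 2 arrays each, and all groups share 1 estimate of the spread per gene. The immobilized mean weighted days 1, 3, 5, 10 and 17 equally. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. For differences among days limma's F-test was used, with at least 1 between the highest and lowest day mean. Gene lists (33, written from general knowledge of yeast) were tested with camera, two-sided, at a preset correlation of 0.01, adjusted over the lists within a comparison; an estimated correlation and fry, which tests the direction of a list without setting it against other genes, were the alternatives. Of the 75 list calls reported, each a list in 1 comparison, 70 lost the call with an estimated correlation.

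Comparisons, tests, lists, the rule for naming genes and most alternatives were chosen before the data were examined. Named genes are the 6 highest and 6 lowest called genes of a comparison whose arrays do not overlap between its sides, the 3 members of a described list with the largest absolute change, and genes fixed in advance, 24 of which were measured without missing values. The absence of overlap is therefore a condition for naming and no separate evidence. Further alternatives, chosen after seeing the data, concerned arrays with next to no dap spike, arrays with high ACT1 3' signal, replicates 1 and 2 against 3 and 4, day 10 in the mean, fry and a filter on genes that hardly vary. The alternatives fixed beforehand were quantile normalization repeated over the genes, a shift of each array to 1 median, averaged probe sets, no fold minimum, a trended and robust prior, array weights, only the groups of a comparison, the replicate number as a block, other sets and weights of days, and leaving out each array in turn, where a lone array is assumed to vary like the other groups. A planned filter on dim probe sets could not be run on ratios.

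Whether equal replicate numbers pair arrays of different days was checked by the correlation of their deviations from the day means. It held for day 5 against day 3, with correlations of 0.864, 0.548, 0.854 and 0.793. The replicate block, fitted with a shared effect per number over all groups, gave 0 called genes there, as without it. A fit that pairs only these days was not run, so that 0 says nothing about a paired comparison. In the other day comparisons the numbers did not match arrays in this way, so no block was used. The procedure was tested on simulated data with 200 changed genes of 5445 over 10 simulations. A log2 change of 1.5 was recovered in 62.7% of changed genes for 2 against 2 arrays. For immobilized against log phase it was 80.8%, and false calls averaged 8.8 and 4.5. The simulated arrays were independent, with the same spread of a gene in all groups. In the data the median SD of a gene ran from 0.0930 in the chemostat to 0.482 at day 1. Arrays of days 3 and 5 also deviated together, so the real rates may differ. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.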

Results

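Transcript levels were measured on 26 Affymetrix yeast expression arrays of a haploid S288C strain of mating type alpha, the standard laboratory yeast. Free (planktonic) cells came from an anaerobic batch culture started at 10 g/L glucose, harvested at 12 h in logarithmic growth (log phase, 2 arrays) or at 72 h in stationary phase (2 arrays). An anaerobic chemostat fed 1 g/L glucose at a dilution rate of 0.15 per h gave 2 further arrays. Another 18 arrays came from cells enclosed in 3 mm calcium alginate beads, packed in a reactor fed with medium of 100 g/L glucose, at days 1, 3 and 5 (4 arrays each) and days 10 and 17 (3 arrays each). The last 2 arrays are of day 0, which the sample titles place before immobilization and the source names right after it. The series concerns ageing over time in cells that are well fed but hardly divide, so the comparisons ask how immobilized cells differ from growing, starved and slowly growing free cells, and whether they go on changing between day 1 and day 17. Nothing in the labels says that arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision. Changes are log2 fold changes ± SE from limma over 5445 genes. They are relative to the median of each array, which lay near a ratio of 1 throughout, so a like change of all messenger RNA would not show. A gene was called changed at an adjusted p under 0.05 with at least a 2-fold difference.

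The first 3 principal components held 37.1%, 21.5% and 11.9% of the variance. The median SD of a gene within a group was 0.0930 in the chemostat, 0.150 in log phase, 0.169 in stationary phase and 0.169 at day 0. Among immobilized cells it was 0.482 at day 1, 0.337 at day 3, 0.390 at day 5, 0.244 at day 10 and 0.254 at day 17.

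**Figure D1:**
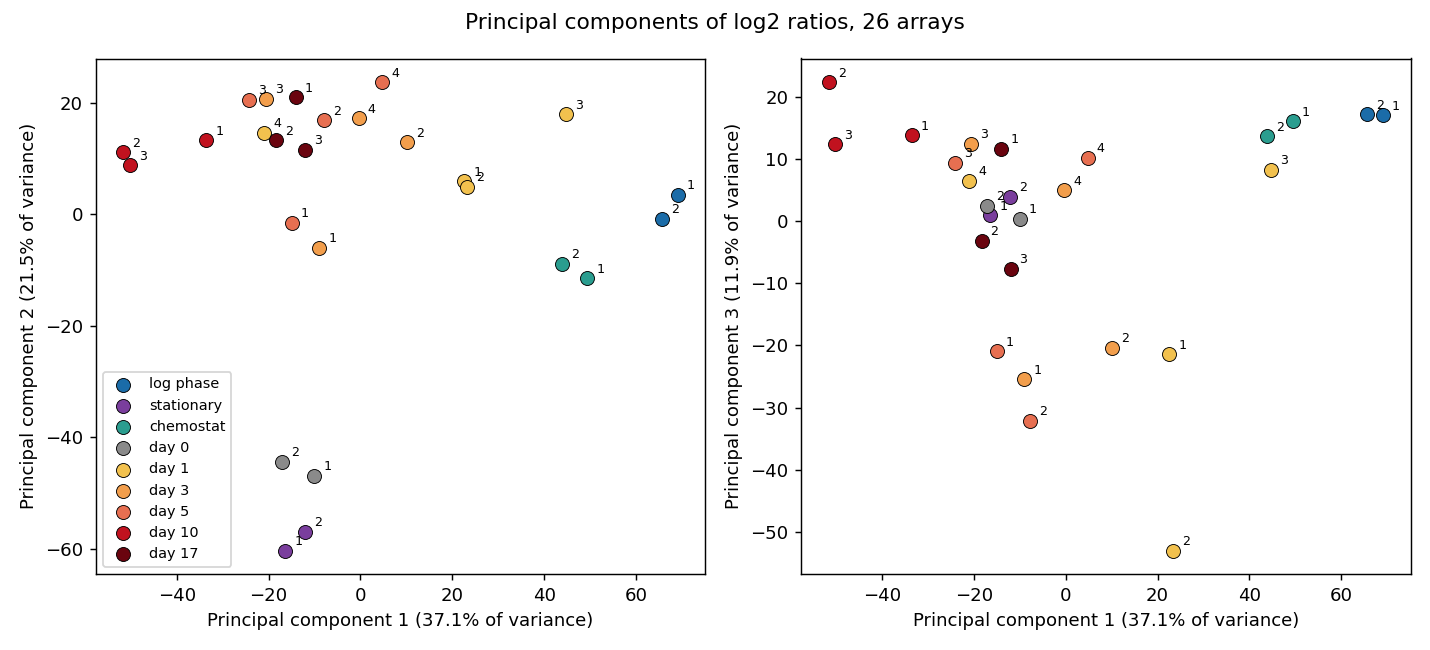
Principal components of the log2 ratios of 5445 genes, with component 1 (37.1% of the variance) on both horizontal axes and components 2 (21.5%) and 3 (11.9%) on the vertical axes. Each point is 1 of the 26 arrays, coloured by group and numbered by replicate. The chemostat and log-phase arrays lie on the right, with day 1 replicate 3 among them at 44.7 between the chemostat arrays at 43.9 and 49.4. The stationary-phase and day 0 arrays lie at the bottom of component 2. Replicates 1 and 2 of days 1, 3 and 5 lie at -53 to -20.4 on component 3 against 4.96 to 12.5 for replicates 3 and 4.

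Immobilized cells (the mean of days 1 to 17, 18 arrays) were first set against log-phase cells (2 arrays). Among tested genes whose arrays did not overlap, the highest rise was in RSB1 (YOR049C), which moves sphingoid long-chain bases across the plasma membrane, at 6.51 ± 0.47. SHH3 (YMR118C) followed at 6.35 ± 0.42 and PAU5 (YFL020C) of the anaerobically induced seripauperin family at 6.14 ± 0.23. YOR338W rose by 5.90 ± 0.40, SPG4 (YMR107W), needed for survival in stationary phase, by 5.74 ± 0.89, and HSP30 (YCR021C), a stress protein of the plasma membrane, by 5.49 ± 0.21. The deepest falls were in the cell wall protein gene TOS6 (YNL300W) at -4.32 ± 1.02, the mitotic cyclin gene CLB2 (YPR119W) at -3.97 ± 0.54, CHS2 (YBR038W), the chitin synthase of the septum, at -3.79 ± 0.56, and the uracil salvage gene FUR1 (YHR128W) at -3.78 ± 0.44. SFG1 (YOR315W) at -3.69 ± 0.51 and SWI5 (YDR146C), a transcription factor of late mitosis, at -3.68 ± 0.46 completed the 6 lowest. For each of these 12 genes the 18 immobilized arrays lay on 1 side of both log-phase arrays, with adjusted p of at most 0.00173. In all, 1662 genes were called, 864 higher and 798 lower. SPG1 and SPS100, without a value in log phase, and NCA3, with 1 such value, were not tested and so not ranked.

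Genes of growth and division were lower in immobilized than in log-phase cells. Of 128 ribosomal protein genes, 86 fell and 0 rose (86 adjusted over the list alone). Their median was -1.27, with camera's adjusted p = 8.27e-22, or adjusted p = 0.317 with an estimated correlation. RPL9A stood at -3.13 ± 0.59, RPL18B at -2.52 ± 0.29 and RPS22A at -2.49 ± 0.50. In ribosome biogenesis 20 of 50 genes fell (20 adjusted over the list alone). RPA43 stood at -2.88 ± 0.55 and NOP56 at -2.57 ± 0.46, and the list had adjusted p = 7.81e-05, or adjusted p = 0.511 with an estimated correlation. Of 22 genes of G2 and M phase 13 fell (14 adjusted over the list alone). Their median was -1.17, with adjusted p = 3.34e-06, or adjusted p = 0.267 with an estimated correlation. Of 31 genes of G1/S and DNA replication 11 fell (11 adjusted over the list alone). CDC21 stood at -3.04 ± 0.47 and the cyclin genes PCL1 at -3.04 ± 0.70 and CLB6 at -2.92 ± 0.36, and the list had adjusted p = 0.000147, or adjusted p = 0.374 with an estimated correlation. Among 49 amino acid synthesis genes controlled by Gcn4, 30 fell (30 adjusted over the list alone). TRP4 stood at -2.52 ± 0.39, LYS9 at -2.66 ± 0.66 and THR1 at -2.36 ± 0.54, and the list had adjusted p = 2.19e-07, or adjusted p = 0.317 with an estimated correlation.

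Genes known from quiescence, stress and poor carbon sources were higher. Of 19 quiescence and stationary-phase genes 15 rose (15 adjusted over the list alone). Their median was 2.15, with adjusted p = 1.17e-08, or adjusted p = 0.172 with an estimated correlation, and MOH1 at 4.99 ± 0.23 and SIP18 at 4.97 ± 0.28 followed SPG4. In gluconeogenesis, the glyoxylate cycle and fatty acid oxidation 16 of 25 genes rose (18 adjusted over the list alone). POT1 stood at 3.79 ± 0.64, the acyl-CoA oxidase gene POX1 at 3.65 ± 0.46 and the malate synthase gene MLS1 at 3.35 ± 0.69, and the list had adjusted p = 2.95e-05, or adjusted p = 0.374 with an estimated correlation. Of 24 autophagy genes 12 rose (12 adjusted over the list alone). ATG15 stood at 2.65 ± 0.52, ATG1 at 2.31 ± 0.40 and ATG8 at 2.27 ± 0.37, and the list had adjusted p = 2.95e-05, or adjusted p = 0.281 with an estimated correlation. Of 24 Msn2/Msn4 targets 11 rose (11 adjusted over the list alone). GRE1 stood at 4.08 ± 0.53, GPX1 at 3.51 ± 0.40 and XBP1 at 2.56 ± 0.76, and the list had adjusted p = 2.95e-05, or adjusted p = 0.317 with an estimated correlation. Among 22 heat shock genes 7 rose and 1 fell (7 and 1 adjusted over the list alone). SSA3 stood at 3.18 ± 0.49 and SSE2 at 1.62 ± 0.20 after HSP30, and the list had adjusted p = 0.000255, or adjusted p = 0.317 with an estimated correlation.

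The anaerobic and hypoxic genes were higher as well, although the log-phase culture was itself anaerobic; the labels do not say whether the bead reactor was. Of 28 genes 15 rose and 3 fell (15 and 3 adjusted over the list alone). Their median was 1.21, with adjusted p = 3.34e-06, or adjusted p = 0.172 with an estimated correlation. PAU2 at 5.30 ± 0.23 and PAU24 at 5.11 ± 0.36 followed PAU5. The probe sets of these 3 near-identical genes can also bind other family members. The anaerobic gene DAN1, left out for missing values at day 0, hardly rose, with a mean log2 ratio of -0.20 in log phase and -0.03 to 0.35 at days 1 to 17. Of 34 cell wall genes 13 rose and 4 fell (13 and 4 adjusted over the list alone): the flocculin gene FLO1 rose by 5.11 ± 0.46 and PIR3 by 4.93 ± 0.21, while the transglycosylase gene UTR2 fell by 3.33 ± 0.55, and the list had adjusted p = 0.00919, or adjusted p = 0.506 with an estimated correlation. Glycolysis as a list of 16 genes was not called, with a median of -0.19 and adjusted p = 0.204; the hexokinase gene HXK2, lower by -2.53 ± 0.38, was its 1 called member, and PFK2 at -1.01 ± 0.43 and PYK2 at -0.90 ± 0.27 were not called. Of the 24 measured genes fixed in advance 5 rose and 2 fell. CTT1, the cytosolic catalase gene, rose by 2.32 ± 0.31, HSP26 by 1.23 ± 0.13, the quiescence kinase gene RIM15 by 1.53 ± 0.18, and the hexose transporter genes HXT5 and HXT1 by 5.06 ± 0.27 and 2.99 ± 0.64. Besides CLB2, the G1 cyclin gene CLN2 fell by 1.32 ± 0.54. ACT1 at -0.02 ± 0.14, PDC1 at -0.19 ± 0.34, ADH1 at -0.19 ± 0.17, HSP12 at 0.58 ± 0.18 and SIR2 at 0.34 ± 0.27 were not called. With quantile normalization repeated over the genes 516 genes were called (307 higher, 209 lower), and XBP1, PCL1, ATG1, LYS9, THR1, HSP26, CLN2 and HXT1 lost the call. XBP1 and ATG15 (then 0.97) also lost it without log phase replicate 1, HXT1 without log phase replicate 2, and CLN2 without either of them or without any 1 of 12 other arrays. RNA was extracted by different published methods from beads and from free cells, so in every comparison of the 2 kinds culture and extraction cannot be told apart. The mean 3' minus 5' difference of 6 control genes (log2), a sign of RNA quality, also differed between them on average, although single arrays at day 1 ranged from -0.363 to 0.605. It was -0.367 in log phase, -0.353 in the chemostat, -0.189 in stationary phase and -0.202 at day 0, against 0.0234, 0.110, 0.189, 0.106 and 0.299 at days 1, 3, 5, 10 and 17.

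**Figure D2:**
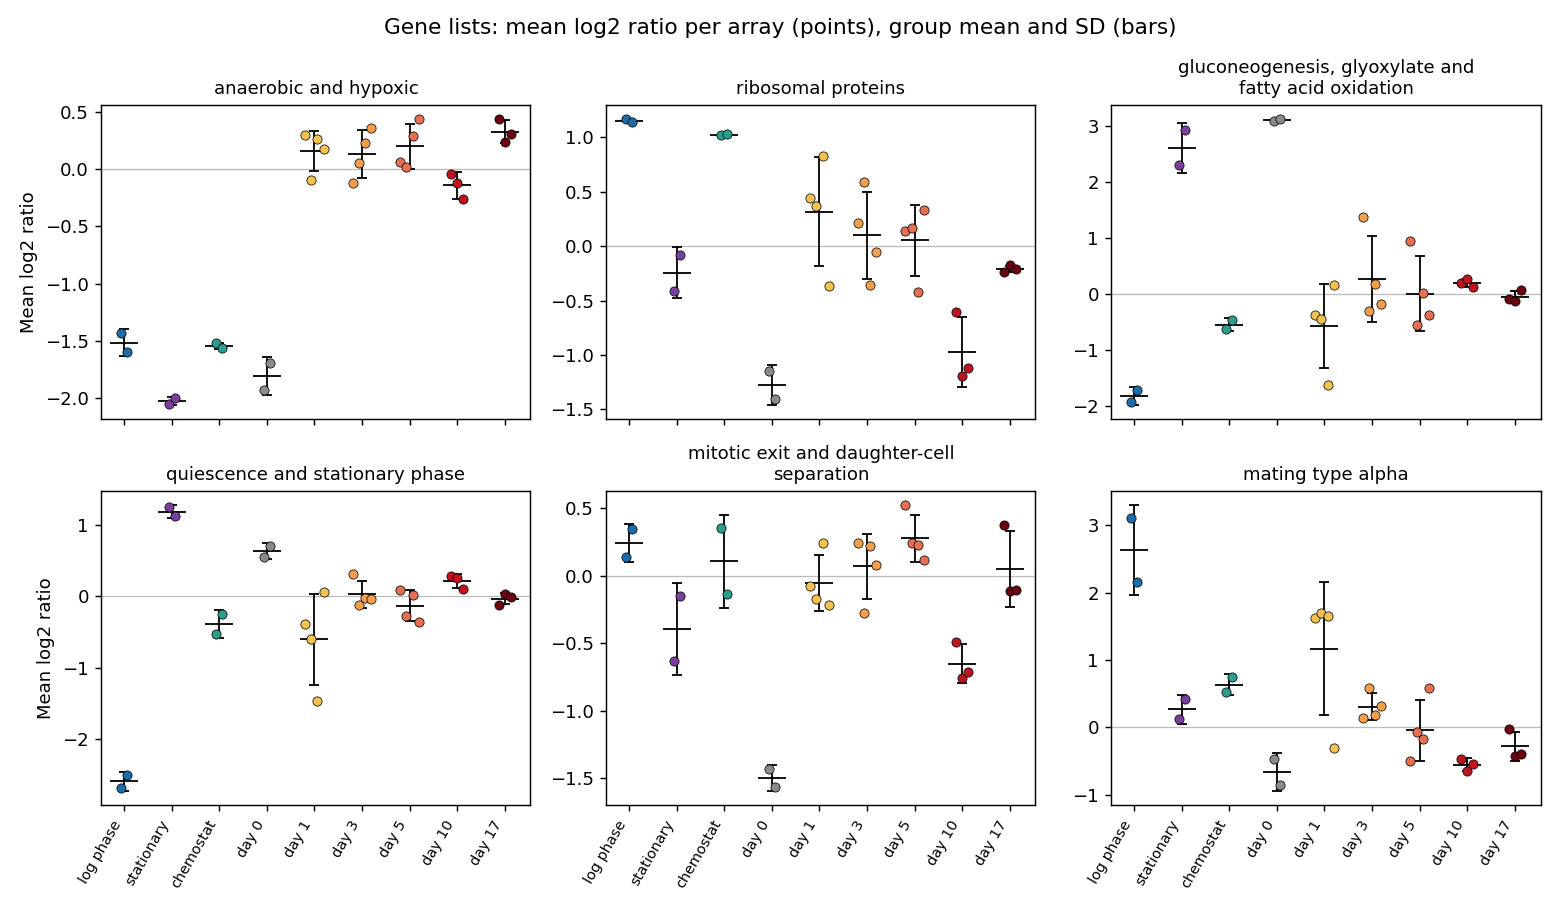
Mean log2 ratio over the genes of 6 lists (vertical axes) in the 9 groups (horizontal axes); points are single arrays, the long bar is the group mean and the whiskers are 1 SD. The anaerobic list averages -1.52 in log phase and 0.159 at day 1, and the ribosomal protein list 1.15 in log phase, -1.28 at day 0 and -0.974 at day 10.

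Against stationary phase (2 arrays) the immobilized cells (18 arrays) had higher anaerobic genes and lower genes for growth on poor carbon sources. PAU5 was higher by 5.88 ± 0.23, PAU2 by 5.51 ± 0.23, HUG1 (YML058W-A), an inhibitor of ribonucleotide reductase, by 5.34 ± 0.33, the mannoprotein gene TIR3 (YIL011W) by 5.17 ± 0.35, YML083C by 5.06 ± 0.45 and PAU24 by 5.02 ± 0.36. RGI2 (YIL057C), a gene of respiratory growth, was lower at -7.14 ± 1.59, the acetate transporter gene ADY2 (YCR010C) at -5.85 ± 0.84, the carnitine acetyltransferase gene YAT1 (YAR035W) at -5.23 ± 0.84, the proline permease gene PUT4 (YOR348C) at -4.37 ± 0.86, the siderophore-binding wall protein gene FIT2 (YOR382W) at -4.37 ± 0.45 and PCK1 (YKR097W), which starts gluconeogenesis, at -4.15 ± 0.57. Arrays of the 2 sides did not overlap for these 12 genes, whose adjusted p was at most 0.00113. There were 1431 called genes, 645 higher (45.1%) and 786 lower.

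Of the 28 anaerobic genes 21 were higher and 1 lower in immobilized than in stationary-phase cells (21 and 1 adjusted over the list alone). Their median was 2.11, with adjusted p = 3.86e-12, or adjusted p = 0.0176 with an estimated correlation, so this list's call held. Of 24 sterol synthesis genes 17 were higher (18 adjusted over the list alone). ERG5 stood at 2.90 ± 0.26, ERG26 at 2.85 ± 0.32 and the squalene epoxidase gene ERG1 at 2.41 ± 0.25, and the list had adjusted p = 7.07e-10, or adjusted p = 0.353 with an estimated correlation. Of 34 cell wall genes 19 were higher and 1 lower (19 and 1 adjusted over the list alone). FLO1 stood at 4.73 ± 0.46, YPS3 at 4.40 ± 0.71 and PST1 at 3.71 ± 0.17, and the list had adjusted p = 1.52e-07, or adjusted p = 0.481 with an estimated correlation. In the gluconeogenesis list 22 of 25 genes were lower (22 adjusted over the list alone). Their median was -2.50, with adjusted p = 1.69e-08, or adjusted p = 0.481 with an estimated correlation. Of 38 respiration genes 18 were lower (21 adjusted over the list alone), with NDE2, an external NADH dehydrogenase of mitochondria, at -2.88 ± 0.35, CYC1 at -2.98 ± 1.08 and COX6 at -2.19 ± 0.57, and the list had adjusted p = 4.83e-06, or adjusted p = 0.841 with an estimated correlation. Of 19 TCA cycle genes 7 were lower (7 adjusted over the list alone). CIT3 stood at -3.37 ± 0.48 and FUM1 at -1.86 ± 0.36, and the list had adjusted p = 0.0364, or adjusted p = 0.913 with an estimated correlation. Of the 19 quiescence genes 9 were lower (9 adjusted over the list alone). POT1 stood at -4.01 ± 0.64, FMP45 at -3.97 ± 0.62 and GRE1 at -2.61 ± 0.53, and the list had adjusted p = 0.0112, or adjusted p = 0.731 with an estimated correlation. Of the 24 autophagy genes 7 were lower and 1 higher (7 and 1 adjusted over the list alone). ATG34 stood at -1.88 ± 0.22, ATG29 at -1.59 ± 0.23 and ATG5 at 1.61 ± 0.25, and the list had adjusted p = 0.0112, or adjusted p = 0.731 with an estimated correlation.

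Among the genes fixed in advance 3 were higher and 5 lower than in stationary phase. RIM15 was higher by 1.20 ± 0.18, HXT1 by 2.35 ± 0.64 and the G1 cyclin gene CLN3 by 1.43 ± 0.54. The cyclin-dependent kinase inhibitor gene SIC1 was lower at -1.80 ± 0.24, the alcohol dehydrogenase gene ADH2 at -1.44 ± 0.27, the isocitrate lyase gene ICL1 at -3.16 ± 0.55, HXT5 at -1.16 ± 0.27, and CYC1 as above. Of 16 glycolysis genes 3 were higher and 1 lower (3 and 1 adjusted over the list alone). ENO1 stood at 1.71 ± 0.20, PGK1 at 1.67 ± 0.24 and PYK2 at -1.41 ± 0.27, and the list had adjusted p = 0.048, or adjusted p = 0.913 with an estimated correlation. The 2 stationary-phase arrays carried more signal from the poly-A spikes than the other groups, with a mean log2 ratio of 2.55 against -0.39 in log phase. Repeated quantile normalization left 562 calls, 344 higher (61.2%) and 218 lower, and ended those of RGI2, PYK2, CYC1, COX6, GRE1, CLN3, HXT1, HXT5 and the glycolysis list. CYC1 and COX6 lost the call without either stationary-phase array, CLN3 and HXT1 without stationary phase replicate 1, HXT5 when the mean began at day 3 (-0.98) or took days 10 and 17 (-0.81), and ADH2 (-0.89) and CYC1 (-2.89) with days 10 and 17. CYC1 and CLN3 lost it with the replicate number as a replicate block (-2.27 and 1.12), CLN3 with only the groups compared in the model, the TCA list without stationary phase replicate 2 or day 1 replicate 4, and the glycolysis list without any 1 of 19 arrays.

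Genes called both in immobilized against log-phase cells and in stationary-phase against log-phase cells numbered 1079 in the same direction (534 higher, 545 lower) and 27 in opposite directions. Independent lists of these sizes would share 197 higher and 173 lower genes. In 100 simulations of unchanged groups against the same log-phase arrays the overlap averaged 0.01 and reached 1 at most. Unchanged groups have next to no called genes, so this overlap had to be small. It does not show how much 2 changed groups with shared controls would have in common. The covariance of the log2 fold changes was 1.21 against 0.103 in the simulations, a difference of 1.11, and their correlation across genes, which are not independent replicates, was 0.707 against 0.667. Another 556 genes were called in immobilized cells alone and 1315 in stationary phase alone, which by itself does not show that these genes differed between the 2 states. Only 2 log-phase arrays exist. A split of them, with 1 for each comparison, was not made, so part of the excess may come from sharing them. With repeated quantile normalization the overlap was 144.

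Against the glucose-limited chemostat (2 arrays), immobilized cells (18 arrays) had more RSB1 (6.36 ± 0.47), PAU5 (5.76 ± 0.23), YDL114W (5.12 ± 0.80), the low-affinity glucose transporter HXT1 (YHR094C, 5.10 ± 0.64), FLO1 (YAR050W, 4.92 ± 0.46) and YML083C (4.68 ± 0.45). They had less TOS6 (-4.29 ± 1.02), the glutamine permease GNP1 (-4.07 ± 0.73), the cyclin PCL1 (-3.70 ± 0.70), the sulfate permease SUL1 (-3.64 ± 0.77), the tryptophan permease TAT2 (-3.30 ± 0.32) and the cohesin subunit MCD1 (-3.27 ± 0.31). The 2 sides did not overlap for these 12 genes, with adjusted p of at most 0.00319. Of 15 hexose transport genes 4 rose (4 adjusted over the list alone). HXT3 stood at 4.59 ± 0.39 and HXT4 at 2.98 ± 0.50 after HXT1, and the list had adjusted p = 0.0159, or adjusted p = 0.294 with an estimated correlation. Of the 28 anaerobic genes 16 rose and 1 fell (17 and 1 adjusted over the list alone). PAU3 stood at 4.35 ± 0.38 and PAU2 at 4.34 ± 0.23, with a median of 1.57, adjusted p = 1.14e-11, or adjusted p = 0.0254 with an estimated correlation, so the call held although the chemostat was anaerobic too.

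Ribosomal protein genes were lower than in the chemostat in 72 of 128 cases (72 adjusted over the list alone). Their median was -1.14, with RPL9A at -2.77 ± 0.59, RPS0A at -2.33 ± 0.45 and RPS9B at -2.17 ± 0.53, and the list had adjusted p = 5.86e-25, or adjusted p = 0.474 with an estimated correlation. Of the 49 Gcn4 targets 29 fell (29 adjusted over the list alone). TRP4 stood at -3.06 ± 0.39 and ARO4 at -2.73 ± 0.43, and the list had adjusted p = 3.33e-12, or adjusted p = 0.294 with an estimated correlation. Of 22 G2/M genes 11 fell (11 adjusted over the list alone). CLB2 stood at -3.17 ± 0.54, SWI5 at -2.96 ± 0.46 and CHS2 at -2.88 ± 0.56, and the list had adjusted p = 1.71e-05, or adjusted p = 0.294 with an estimated correlation. Of 31 G1/S genes 9 fell (9 adjusted over the list alone). CLN1 stood at -2.87 ± 0.44 and RNR1 at -2.82 ± 0.70, and the list had adjusted p = 0.000377, or adjusted p = 0.518 with an estimated correlation. Of the genes fixed in advance HXT1 rose and CLB2, ADH2 (-1.27 ± 0.27) and CYC1 (-2.88 ± 1.08) fell. The comparison gave 1061 calls, 520 higher (49.0%) and 541 lower, but 418 without chemostat replicate 1, which also ended those of TOS6, SUL1, ADH2, RPS9B, RNR1 and CYC1, and 657 without chemostat replicate 2, which also ended those of RPS9B, RNR1 and CYC1; CYC1 was further not called without any 1 of 15 other arrays, and ADH2 with the mean of days 10 and 17 (-0.73). With repeated quantile normalization 557 genes were called, 350 higher (62.8%) and 207 lower, and RPL9A, RPS9B, RNR1 and CYC1 were not among them.

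**Figure D3:**
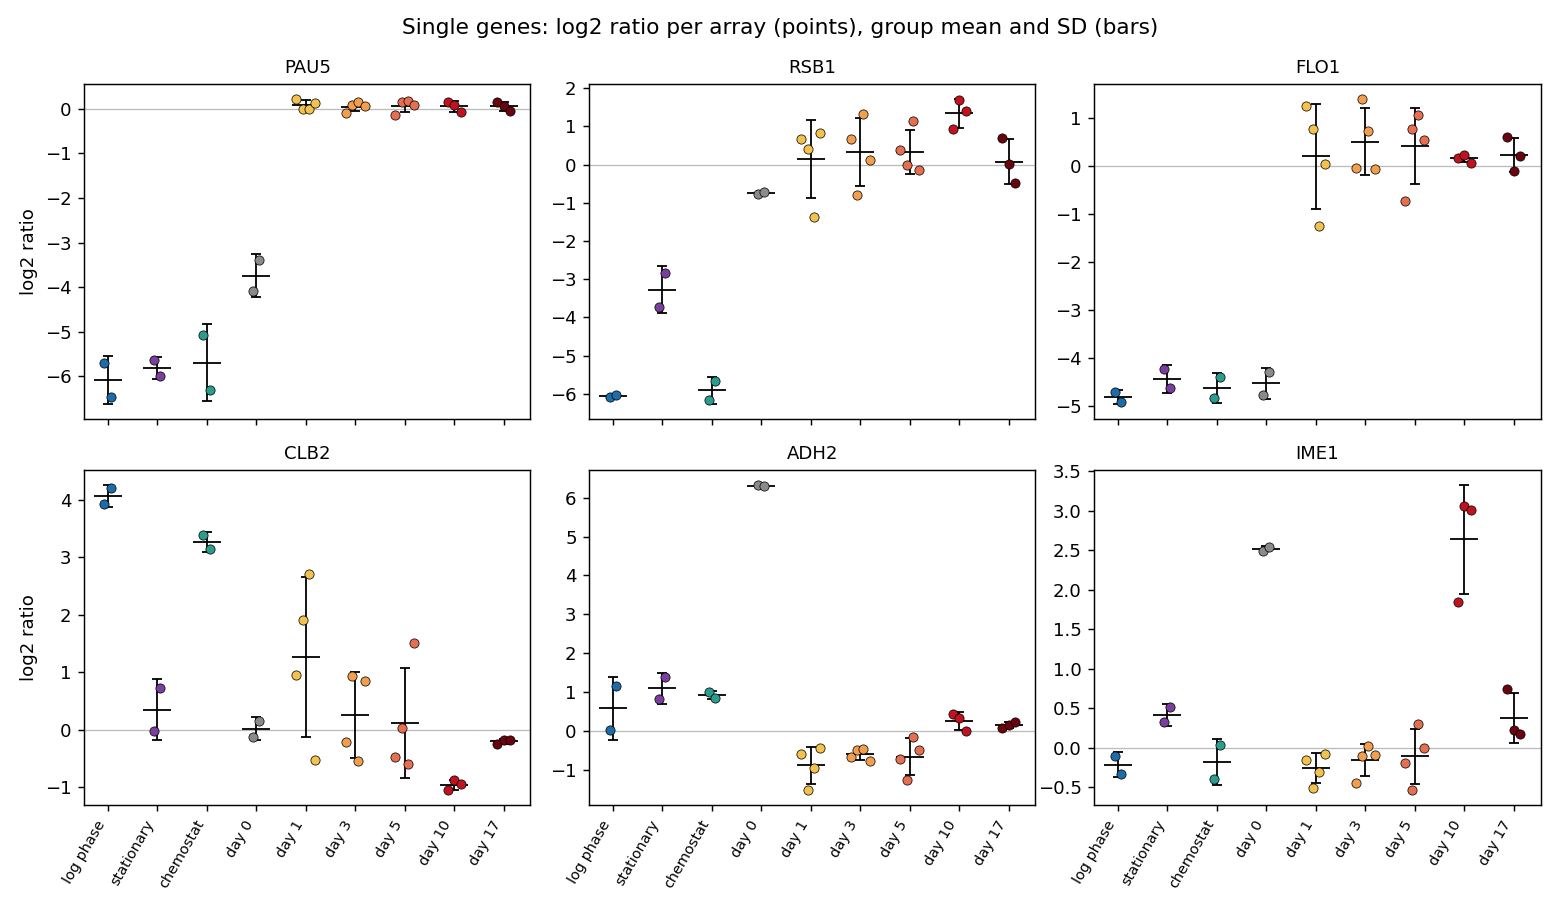
Log2 ratios (vertical axes) of 6 genes in the 9 groups (horizontal axes); points are single arrays, the long bar is the group mean and the whiskers are 1 SD. FLO1 rose by 5.11 ± 0.46 from log phase to the mean of days 1 to 17, ADH2 fell by 7.19 ± 0.32 from day 0 to day 1, and IME1 was higher at day 10 than at day 5 by 2.75 ± 0.25.

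Between day 0 (2 arrays) and day 1 (4 arrays) the genes of growth on acetate and fatty acids fell and those of ribosomes, anaerobic growth and sterol synthesis rose. HES1 (YOR237W), an oxysterol-binding protein gene, rose by 6.06 ± 0.36, INA1 (YLR413W) by 5.30 ± 0.29, TIR1 (YER011W) by 5.19 ± 0.21, SRD1 (YCR018C) by 5.18 ± 0.52, FLO1 by 4.73 ± 0.53 and IZH4 (YOL101C) by 4.60 ± 0.30. The phosphate transporter gene PHO89 (YBR296C) fell with a change of -7.21 ± 0.93, ADH2 (YMR303C) with -7.19 ± 0.32 and ADY2 with -7.03 ± 0.97. The succinate-fumarate carrier gene SFC1 (YJR095W) had -6.53 ± 0.96, YAT1 -6.03 ± 0.97 and the carnitine carrier gene CRC1 (YOR100C) -5.63 ± 0.84. The arrays of the 2 days did not overlap for these 12 genes, with adjusted p of at most 9.5e-05. In all 1106 genes were called, 543 higher and 563 lower.

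Of the 25 gluconeogenesis genes 24 fell between day 0 and day 1 (24 adjusted over the list alone), with adjusted p = 1.36e-15, or adjusted p = 0.125 with an estimated correlation. Of 128 ribosomal protein genes 105 rose (105 adjusted over the list alone). Their median was 1.62, with RPS9A at 3.56 ± 0.32 and RPS22A at 3.27 ± 0.58, and the list had adjusted p = 1.4e-34, or adjusted p = 0.254 with an estimated correlation. Of the 28 anaerobic genes 19 rose and 1 fell (19 and 1 adjusted over the list alone). Their median was 2.26, with TIR3 at 4.47 ± 0.41 and PAU2 at 4.28 ± 0.27, and the list had adjusted p = 2.61e-14, or adjusted p = 0.00949 with an estimated correlation, so the call held. Of 24 sterol synthesis genes 14 rose (14 adjusted over the list alone). ERG5 stood at 3.01 ± 0.30, ERG4 at 2.94 ± 0.28 and ERG3 at 2.46 ± 0.25, and the list had adjusted p = 1.28e-10, or adjusted p = 0.125 with an estimated correlation. Of 18 genes of mitotic exit and daughter-cell separation 11 rose (11 adjusted over the list alone). DSE2 stood at 3.34 ± 0.40 and SCW11 at 2.48 ± 0.37, and the list had adjusted p = 1.98e-06, or adjusted p = 0.125 with an estimated correlation. Of 38 respiration genes 7 fell (7 adjusted over the list alone). NDE2 stood at -2.66 ± 0.40 and CYC1 at -4.54 ± 1.26, and the list had adjusted p = 1.09e-05, or adjusted p = 0.659 with an estimated correlation. HXT5 at -1.63 ± 0.31, ICL1 at -4.29 ± 0.64, ENO2 at 1.80 ± 0.51 and HXT1 at 2.59 ± 0.74 were the other called genes among those fixed in advance. Without day 0 replicate 2 the count fell to 667 and ENO2, HXT1 and CYC1 lost the call, HXT1 and CYC1 also without day 0 replicate 1. With only these 2 groups in the model 454 genes were called, without HXT1 and HXT5. With repeated quantile normalization 429 genes were called, and YAT1, RPS22A, CYC1, HXT1 and ENO2 were not.

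The mean of days 1 to 17 against day 0 (18 and 2 arrays) gave 1027 calls, 541 higher and 486 lower, led by HES1 at 5.85 ± 0.31 and INA1 at 5.67 ± 0.25 and, in the other direction, RGI2 at -6.68 ± 1.59, PHO89 at -6.67 ± 0.80 and ADH2 at -6.66 ± 0.27. The anaerobic list, with 19 of 28 genes higher and 1 lower (19 and 1 adjusted over the list alone) and TIR1 at 5.08 ± 0.18, had adjusted p = 4.59e-14, or adjusted p = 0.00973 with an estimated correlation. The ribosomal protein genes rose in 82 of 128 cases (82 up and 1 down adjusted over the list alone), with adjusted p = 4.77e-22, or adjusted p = 0.435 with an estimated correlation. Of 25 gluconeogenesis genes 21 fell (23 adjusted over the list alone), with adjusted p = 4.95e-14, or adjusted p = 0.142 with an estimated correlation. RGI2 was not called without day 0 replicate 2, and 515 genes were called, without RGI2, after repeated quantile normalization. Day 0 against log phase (2 arrays each) gave 1980 calls, 1013 higher and 967 lower. SFC1 was higher at day 0 by 7.44 ± 1.11 and the fructose bisphosphatase gene FBP1 by 7.16 ± 1.23, while INA1 was lower at -5.65 ± 0.34 and RPS9A at -5.44 ± 0.37. Of 128 ribosomal protein genes 118 were lower (118 adjusted over the list alone), with adjusted p = 1.25e-37, or adjusted p = 0.181 with an estimated correlation, and 24 of 25 gluconeogenesis genes were higher (24 adjusted over the list alone), with adjusted p = 6.45e-15, or adjusted p = 0.181 with an estimated correlation. The anaerobic list went both ways, with 7 genes higher and 12 lower (8 and 12 adjusted over the list alone), and was not called (adjusted p = 0.313). Repeated quantile normalization left 657 calls.

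Stationary-phase cells differed from log-phase cells (2 arrays each) by 2421 called genes, 1241 higher and 1180 lower. Poly-A spike signal was 2.94 (log2) higher in stationary phase, and that of hybridization controls, added after labelling, 0.621 higher. A rise relative to the array median therefore need not be a rise in absolute amount. The peroxisomal genes POT1 (YIL160C), PEX18 (YHR160C) and CTA1 (YDR256C) rose by 7.80 ± 0.85, 7.64 ± 0.72 and 7.20 ± 0.85, SHH3 by 7.62 ± 0.56, SPG4 by 7.17 ± 1.20 and RGI2 by 7.10 ± 2.13. The alcohol acetyltransferase gene ATF2 fell with a change of -4.32 ± 0.72, the cytochrome b5 gene CYB5 with -3.79 ± 0.62 and CLB2 with -3.71 ± 0.73. The sterol gene ERG26 had -3.59 ± 0.43, HAM1 -3.49 ± 0.58 and the eisosome gene SUR7 -3.37 ± 0.46. The arrays of these 12 genes did not overlap, with adjusted p of at most 0.00868. Of 25 gluconeogenesis genes 23 rose (23 adjusted over the list alone). Their median was 4.41, with MLS1 at 7.05 ± 0.93 and ADY2 at 6.63 ± 1.13, and the list had adjusted p = 1.05e-10, or adjusted p = 0.278 with an estimated correlation. Of 19 quiescence genes 16 rose (16 adjusted over the list alone). GRE1 stood at 6.68 ± 0.70, and the list had adjusted p = 2.73e-09, or adjusted p = 0.227 with an estimated correlation. Of 24 autophagy genes 16 rose (17 adjusted over the list alone). ATG8 stood at 3.07 ± 0.49 and ATG15 at 3.49 ± 0.69, and the list had adjusted p = 3.84e-06, or adjusted p = 0.278 with an estimated correlation. Of 38 respiration genes 18 rose (18 adjusted over the list alone). NDE2 stood at 5.28 ± 0.46 and COX7 at 1.97 ± 0.51, and the list had adjusted p = 0.00015, or adjusted p = 0.558 with an estimated correlation.

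In the same comparison 93 of 128 ribosomal protein genes fell (93 adjusted over the list alone). RPL13A stood at -2.98 ± 0.55 and RPS17B at -2.76 ± 0.63, and the list had adjusted p = 2.79e-15, or adjusted p = 0.477 with an estimated correlation. Of 24 sterol synthesis genes 20 fell (20 adjusted over the list alone). MVD1 stood at -3.33 ± 0.47 and ERG5 at -2.93 ± 0.35, and the list had adjusted p = 3.37e-10, or adjusted p = 0.278 with an estimated correlation. Of 22 G2/M genes 16 fell (16 adjusted over the list alone). CHS2 stood at -3.12 ± 0.76, and the list had adjusted p = 4.14e-05, or adjusted p = 0.366 with an estimated correlation. CTT1 rose by 3.00 ± 0.41, HXT5 by 6.22 ± 0.36, ICL1 by 4.09 ± 0.74, SIC1 by 1.32 ± 0.33 and HSP12 by 1.01 ± 0.24, HSP26 rose as well, and ACT1 at -0.70 ± 0.18 was not called. Mean ACT1 signal at the 3' end exceeded that at the 5' end more in stationary than in log phase, by 1.33 (log2). The mean of 5 other control genes differed by -0.05, with single genes from -0.51 to 0.50. Repeated quantile normalization left 623 calls and ended those of RGI2, RPL13A, RPS17B, CHS2, COX7, HSP12, HSP26 and SIC1. RGI2 and HSP26 also lost the call without log phase replicate 1, and HSP12 with every array shifted to 1 median (0.99).

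Between chemostat and log phase (2 arrays each) the differences were fewer: 124 genes, 96 higher (77.4%) and 28 lower. SHH3 was higher in the chemostat by 5.83 ± 0.56, GRE1 by 5.42 ± 0.70, HXT5 by 5.28 ± 0.36, HSP30 by 5.17 ± 0.28, the peptide transporter gene PTR2 by 5.16 ± 0.73 and the amino acid permease gene BAP3 by 5.04 ± 0.70. Lower were the glucose transporter genes HXT4 (-3.62 ± 0.67), HXT2 (-3.04 ± 0.78) and HXT3 (-2.62 ± 0.53), the alpha-factor gene MF(ALPHA)2 (-3.02 ± 0.45), SRD1 (-2.50 ± 0.60) and the alpha-agglutinin gene SAG1 (-2.35 ± 0.41). The arrays of these 12 genes did not overlap, with adjusted p of at most 0.0391. Of 19 quiescence genes 10 rose (12 adjusted over the list alone). SIP18 stood at 4.94 ± 0.37, and the list had adjusted p = 6.16e-20, or adjusted p = 0.00732 with an estimated correlation, so the call held. Of 24 Msn2/Msn4 targets 7 rose (9 adjusted over the list alone), with adjusted p = 5.02e-11, or adjusted p = 0.162 with an estimated correlation, and of 22 heat shock genes 4 rose (4 adjusted over the list alone). SSA3 stood at 3.72 ± 0.66, HSP26 at 1.11 ± 0.17, and the list had adjusted p = 9.15e-08, or adjusted p = 0.19 with an estimated correlation. Of 25 gluconeogenesis genes 3 rose (4 adjusted over the list alone). MDH2 stood at 2.19 ± 0.41, and the list had adjusted p = 1.2e-07, or adjusted p = 0.292 with an estimated correlation; fry did not call this list. CTT1 rose by 2.06 ± 0.41. The count was 39 without log phase replicate 1, 74 without chemostat replicate 1 and 39 without chemostat replicate 2. Log phase replicate 1 decided the calls of HXT2, HXT3, SRD1, SAG1, HSP26, MDH2 and CTT1, log phase replicate 2 those of HXT2 and SRD1, chemostat replicate 1 those of HXT4, HXT2, HXT3 and SRD1, and chemostat replicate 2 those of HXT2, SRD1, MDH2 and CTT1. HXT2 also lost it without day 0 replicate 1, day 0 replicate 2 or day 10 replicate 1, and HXT2 and SRD1 without the 3 arrays of days 10 and 17 with next to no signal from dap, an RNA spike added before labelling. Repeated quantile normalization left 10 calls, 9 higher (90.0%) and 1 lower, which of the genes named here kept SHH3, HXT5, HSP30, MF(ALPHA)2 and SIP18, while array weights gave 360.

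Within the immobilized cells, 1136 genes differed among days 1 to 17 by limma's F-test (18 arrays). Of these 525 had their highest and 457 their lowest mean at day 1, and 480 and 613 at day 10. Without day 10 replicate 2 the number was 284, without day 10 replicate 3 it was 493, and with repeated quantile normalization 346. Without the 3 arrays of days 10 and 17 with next to no dap spike it was 121, with only these groups in the model 695 and with array weights 2247. Between days 1 and 3 (4 arrays each) 1 gene was called, YDL218W at 3.13 ± 0.54 with adjusted p = 0.0472, and 451 genes had an unadjusted p under 0.05. That call was lost with repeated quantile normalization and in 20 of the 26 fits that left out 1 array, while leaving out day 1 replicate 4 gave 254 calls and array weights 311. Between days 3 and 5 (4 arrays each) limma called 0 genes, with 30 at an unadjusted p under 0.05. That is fewer than chance alone gives among 5445 unchanged genes. Arrays of these days with equal replicate numbers deviated together, which the model ignores, so the count of 0 does not show that the profile stayed the same. Camera at the preset correlation called 14 of 33 lists between days 1 and 3 and 13 between days 3 and 5, while with an estimated correlation and by fry 0 lists were called in either comparison.

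Day 10 (3 arrays) differed from day 5 (4 arrays) by 524 genes, 179 higher and 345 lower. Meiotic genes stood among the highest: IME1 (YJR094C), the master regulator of meiosis, rose by 2.75 ± 0.25, the sporulation genes SPO20 and SMK1 by 2.91 ± 0.58 and 2.71 ± 0.77, PUT4 by 3.30 ± 0.88, YMR244W by 3.29 ± 0.78 and YBR182C-A by 2.45 ± 0.37. The daughter-cell genes DSE1 (YER124C) and DSE4 fell with changes of -3.02 ± 0.54 and -2.43 ± 0.31. The glycine cleavage gene GCV1 had -3.06 ± 0.84, UTP13 -2.51 ± 0.60, the adenylate kinase gene ADK1 -2.46 ± 0.54 and the flavohaemoglobin gene YHB1 -2.44 ± 0.41. The arrays of these 12 genes did not overlap, with adjusted p of at most 0.0208. Among the ribosomal protein genes 59 of 128 fell (63 adjusted over the list alone). Their median was -0.98, with RPS22A at -2.33 ± 0.51, and the list had adjusted p = 3.52e-26, or adjusted p = 0.929 with an estimated correlation. Of 18 mitotic exit genes 9 fell (9 adjusted over the list alone), with adjusted p = 0.00108, or adjusted p = 0.929 with an estimated correlation, and of 24 sterol genes 6 fell (6 adjusted over the list alone). ERG13 stood at -2.07 ± 0.44 and ERG2 at -1.84 ± 0.26, and the list had adjusted p = 0.000104, or adjusted p = 0.929 with an estimated correlation. Of 23 meiosis and sporulation genes 5 rose (6 adjusted over the list alone), with adjusted p = 0.00641, or adjusted p = 0.929 with an estimated correlation, a call that fry and repeated quantile normalization did not give. Without day 10 replicate 2 there were 114 calls and PUT4, YMR244W, SMK1, GCV1, UTP13, ADK1 and RPS22A lost theirs, without day 10 replicate 3 there were 278 and PUT4, SMK1 and GCV1 lost theirs, and without day 5 replicate 4 there were 344 and SMK1 lost its own. Repeated quantile normalization left 136 calls and ended those of PUT4, YMR244W, SMK1, GCV1, UTP13 and ADK1, and without the 3 arrays of days 10 and 17 that held next to no dap spike there were 196, without the same 6 genes and ERG13.

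Between day 10 and day 17 (3 arrays each) 276 genes were called, 190 higher and 86 lower. DSE4 rose by 2.12 ± 0.34 and IME1 fell by 2.26 ± 0.27; with ERG2, at 1.76 ± 0.28, these were calls kept whichever single array was left out. PAU24 at 2.24 ± 0.39, YHB1 at 2.22 ± 0.44, DSE1 at 2.16 ± 0.58, ADK1 at 2.15 ± 0.57 and KAP114 at 2.15 ± 0.46 were the other highest genes. YMR244W at -3.00 ± 0.83, SPO20 at -2.72 ± 0.62, DIP5 at -2.43 ± 0.69, YOL014W at -2.30 ± 0.66 and URN1 at -2.26 ± 0.49 were the other lowest. Each of these 10, and PAU3 in the anaerobic list, lost its call without day 10 replicate 2 and without day 17 replicate 3. The arrays of the 12 genes did not overlap, with adjusted p of at most 0.0372. Ribosomal protein genes rose in 16 of 128 cases (34 adjusted over the list alone). Their median was 0.74, with adjusted p = 7.04e-17, or adjusted p = 0.885 with an estimated correlation, and of 24 sterol genes 4 rose (4 adjusted over the list alone), with adjusted p = 1.09e-05, or adjusted p = 0.885 with an estimated correlation; fry did not call the ribosomal list. Of 18 mitotic exit genes 7 rose (8 up and 1 down adjusted over the list alone), with adjusted p = 0.00515, or adjusted p = 0.885 with an estimated correlation, a call lost without day 17 replicate 1. Of 28 anaerobic genes 5 rose (5 adjusted over the list alone). PAU3 stood at 2.06 ± 0.41, and the list had adjusted p = 0.00659, or adjusted p = 0.885 with an estimated correlation. The count of 276 became 8 without day 10 replicate 2, 66 without day 10 replicate 3, 523 without day 10 replicate 1, 153 without day 17 replicate 2 and 8 without day 17 replicate 3. It was 28 after repeated quantile normalization, 0 without the 3 arrays with next to no dap spike, which leaves 1 array of day 17, and 3 with those arrays alone on these 2 days, which leaves 1 of day 10. The log2 changes in these fits kept their direction, at -1.71 and -2.81 for IME1, 2.49 and 1.99 for DSE4 and 1.84 and 1.90 for ERG2. The count was 504 with only these groups in the model, 422 with a block for replicates 1 and 2 against 3 and 4 of days 1, 3 and 5, and 803 with array weights.

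Over the whole course, day 17 (3 arrays) against day 1 (4 arrays) gave 16 called genes, 14 higher (87.5%) and 2 lower. GIT1 (YCR098C), which takes up glycerophosphoinositol, was higher by 2.71 ± 0.57, FCY22 by 2.53 ± 0.49, AAD10 by 2.49 ± 0.44, the phosphate-regulated gene PHM7 (YOL084W) by 2.25 ± 0.44, ECM23 by 1.96 ± 0.39 and YLR154C-H, measured by a probe set that can bind other copies, by 1.86 ± 0.40. YMR209C was lower at -1.06 ± 0.22 and YPL199C at -1.02 ± 0.22, and adjusted p reached 0.0493. None of the 24 genes fixed in advance was called, with 0.14 ± 0.18 for RIM15, -0.07 ± 0.18 for HSP12, 0.29 ± 0.27 for SIR2, -1.46 ± 0.56 for CLB2 and 1.03 ± 0.28 for ADH2. Of 128 ribosomal protein genes 0 were called (0 adjusted over the list alone), with 1099 genes at an unadjusted p under 0.05 among the 5445; the list's median was -0.49, camera's adjusted p = 3.54e-16, or adjusted p = 0.692 with an estimated correlation. Of 23 meiosis genes 1 rose (6 adjusted over the list alone), with adjusted p = 1.92e-05, or adjusted p = 0.692 with an estimated correlation. Of 17 phosphate starvation genes 2 rose (3 adjusted over the list alone), with adjusted p = 0.0223, or adjusted p = 0.692 with an estimated correlation, and of 4 alpha-specific genes 0 were called (2 down adjusted over the list alone). Their median was -1.16, with adjusted p = 0.0011, or adjusted p = 0.692 with an estimated correlation; fry called none of these 4 lists, and the phosphate list was not called without day 17 replicate 1. Leaving out single arrays gave 0 calls in 17 of 26 fits, 657 without day 1 replicate 4, 47 without day 17 replicate 1, 10 without day 3 replicate 3, 6 without day 5 replicate 3 and 3 without day 3 replicate 1. With only these 2 groups in the model, or without the 3 arrays with next to no dap spike, which leaves 1 array of day 17, limma called 0 genes, but 196 with the replicate number as a replicate block, 203 with the block for replicates 1 and 2 against 3 and 4 of days 1, 3 and 5, and 759 with array weights. Repeated quantile normalization gave 51 calls, 31 higher (60.8%) and 20 lower, and at day 1 the arrays themselves differed, since of 1648 genes that separate the log-phase and chemostat arrays from those of days 3 to 17 replicate 4 had 98.2% on the immobilized side and replicate 3 had 24.4%.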

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

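Tests chosen after the result was seen are those of splits that part tied pairs, of RNA quality and of an even shift at day 10, of the replicate pairs and the anaerobic genes of day 1 replicate 3, and of degraded RNA and messenger RNA amount in stationary phase. The other splits were fixed before the data were examined; the tests of the dap spike batch and of the share of separating genes were chosen after seeing the data but before their own result.

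In all 1136 genes differed among days 1 to 17, a difference between groups tested by limma's F-test; 3 of 100 splits of the 18 arrays gave as many, the highest other 1648. Arrays of days 3 and 5 with equal numbers are tied, and 2 of 100 splits that part each of these 4 pairs, as the real one does, gave as many, the highest other 1229. Both sets of splits ignore that replicates 1 and 2 part from 3 and 4, so chance was not excluded by them. Without day 10 replicate 2 the number was 284, without day 10 replicate 3 it was 493, and without the 3 arrays of next to no dap spike it was 121. For day 10 against day 5, 1 of 35 splits, the real one with 524 genes, gave as many and the highest other gave 364, but these splits too ignore the parting at day 5, so chance was not excluded. For day 17 against day 10 the 10 splits are too few for a share under 5%; the real split gave 276 genes and the highest other 17. For day 17 against day 1, 5 of 35 splits gave at least the real 16, the highest 745 with day 1 replicates 1 to 3 on a side of their own, and for day 3 against day 1, 6 of 35 gave at least the real 1, the highest 461, so chance was not excluded for either and the higher counts point to a structure among the arrays. For day 5 against day 3 the real count was 0, which each of the 35 splits reaches by definition (35 of 35), so they say nothing about chance; the split of replicates 1 and 2 from 3 and 4 gave 502, and the 8 splits that part each of the 4 pairs gave 0.

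The 3 day 10 arrays stood apart from those of days 5 and 17. With the 3 arrays of next to no dap spike as a spike block, day 10 against day 5 gave 426 called genes against 524 without it, which argues against that batch as the whole cause, although leaving those arrays out gave 196. The mean 3' minus 5' difference of the control genes was 0.106 at day 10 (SD 0.118). It was 0.189 at day 5 (SD 0.332) and 0.299 at day 17 (SD 0.147). The mean was thus not higher at day 10, but with this spread between arrays poorer RNA was not excluded. The median change of all genes was -0.0265, but each deposited array was already scaled to a median ratio near 1. This value therefore says nothing about an even shift by the scaling. An even shift alone would move all genes alike, so it could not by itself give 179 genes called higher and 345 lower at day 10 than at day 5. Scaling each array to 1 median yields changes on both sides in any case, so these counts do not show whether it moved some of the genes. A part of an even shift therefore stayed open. Time in the beads and any handling shared by the day 10 samples may each remain a cause and were not tested apart.

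At days 1, 3 and 5 replicates 1 and 2 parted from replicates 3 and 4 on component 3. The 3' minus 5' difference parted the same pairs in 3 days of 3, with replicates 1 and 2 at most -0.194 and replicates 3 and 4 at least 0.0457 at day 1, so RNA quality or handling may contribute. No biological explanation was tested, since the labels give no group that follows these pairs. The 1648 genes used here separate the log-phase and chemostat arrays from those of days 3 to 17. Stationary phase and day 0 played no part in choosing them. In day 1 replicate 3, 24.4% lay on the side of days 3 to 17, against 53.5% to 98.2% in the other day 1 arrays. That share lay between the bounds set for and against a log-phase array. The anaerobic list of day 1 replicate 3 averaged 0.263, within the -0.265 to 0.439 of days 3 to 17. This was far above the -1.60 and -1.43 of log phase (SD 0.119), which argues against a log-phase array under a wrong label. PAU5 stood at -0.01 in it against -5.70 and -6.46 in log phase, and FLO1 at -1.26 against -4.71 and -4.91. Why this array lay nearer to log phase than the other day 1 arrays stayed open.

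The stationary-phase arrays held more poly-A spike signal than the log-phase arrays, with a mean log2 ratio of 2.55 in stationary phase, in probe sets that no comparison used. The 3' minus 5' signal of ACT1 averaged 1.19 there, but the mean of the other 5 control genes differed from log phase by -0.0511. Single genes of these 5 differed by -0.506 to 0.502. Their mean was thus not higher, but with this spread and 2 arrays in each group degraded RNA was not excluded. Less yeast messenger RNA in the labelled amount, a biological as well as a technical possibility, may be the cause and stayed open: the poly-A difference of 2.94 came with 0.621 in hybridization controls, which such a cause should leave alone.

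A dap spike mean of -5.04 was seen in day 10 replicate 3 and day 17 replicates 2 and 3, against -2.88 to 2.52 in the other 23 arrays. Among 171 sets of 4 arrays 9 had 1 array far from the others. This is about as many as chance gives, at 1 in 20, so the cases listed here may be chance alone. At day 1 these were HXT7, lowest in replicate 3 at -1.39, whose probe set can bind related transporter genes, HXT5, highest in replicate 4 at 0.0115, ENO2, highest in replicate 3 at 0.616, and the mean of the alpha-specific genes, lowest in replicate 4 at -0.31. At day 3 they were ADH1 at -0.468 and ENO2 at -1.51, lowest in replicate 1, and the mean of the lifespan list, lowest in replicate 2 at -0.0559. At day 5 they were ACT1, lowest at -0.386, and ICL1, highest at 1.41, both in replicate 1.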

How the results depend on the processing

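Tests chosen after the data were seen are those with the dap spike, the ACT1 3' signal, the run block, fry, the immobilized mean without day 10 and the filter on genes that hardly vary. Of 563 named-gene values, each a gene in 1 comparison, 328 were called. Over the alternatives 12824 of their 13469 values kept the call, 645 lost it and 0 reversed, and 210 of the 328 kept it throughout. Apart from those fixed in advance, these genes were chosen for large changes, and many alternatives leave out 1 array, often outside the comparison. The share kept therefore does not describe called genes in general. Over all genes, repeated quantile normalization took 1662 calls of immobilized against log phase to 516 and 124 of chemostat against log phase to 10. Of 75 list calls, each a list in 1 comparison, 66 kept the call throughout these alternatives, apart from the list tests: with an estimated correlation 70 lost it, and with fry 8.

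Repeated quantile normalization gave 516 called genes for immobilized against log phase, 562 against stationary phase, 557 against chemostat and 515 against day 0, 429 for day 1 against day 0, 51 for day 17 against day 1, 623 for stationary against log phase, 10 for chemostat against log phase, 657 for day 0 against log phase, 0 for day 3 against day 1, 136 for day 10 against day 5, 28 for day 17 against day 10, 346 among days and 144 in the overlap. It forces 1 distribution of ratios on all arrays and so evens out their spread by construction; it ended 93 gene calls and 5 list calls, counted per comparison.

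With no fold minimum, which can only add calls, there were 2704, 2391, 1845 and 1841 for immobilized against log phase, stationary phase, chemostat and day 0, 1014 for day 10 against day 5, 461 for day 17 against day 10 and 1747 in the overlap. For day 17 against day 1 the count of 16 became 7 with a trended and robust prior, 759 with array weights, 0 with only its groups, 196 with the replicate block, 203 with the run block, 0 with the spike block, 0 without the 3 arrays of next to no dap spike and 0 without the arrays of high ACT1 3' signal, and from 0 to 657 (without day 1 replicate 4) with 1 array left out. For day 3 against day 1 the count of 1 became 0 with a trended and robust prior, 311 with array weights, 0 with only its groups, 0 with the spike block, 0 without the dap-poor arrays, 0 without those of high ACT1 3' signal, and 0 to 254 with 1 array left out. Array weights, whose estimation stopped before it reached its tolerance, gave 360 for chemostat against log phase, 803 for day 17 against day 10 and 2247 among days. Only the groups compared gave 454 for day 1 against day 0, 504 for day 17 against day 10 and 695 among days. Without the dap-poor arrays there were 196 for day 10 against day 5, 0 for day 17 against day 10 and 121 among days, with fewer arrays (1 left at day 17); with those arrays alone on both days, day 17 against day 10 gave 3, and with the run block 422. Except where stated the cause was not tested.

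Leaving out 1 array gave 418 to 1153 for immobilized against chemostat, 667 to 1333 for day 1 against day 0, 39 to 159 for chemostat against log phase, 114 to 744 for day 10 against day 5, 8 to 523 for day 17 against day 10 and 284 to 1686 among days. The planned filter on dim probe sets was not run, because ratios hold no brightness, and what signal over background limits is therefore unknown. The filter used in its place kept 5331 genes (97.9%), whose SD over the arrays exceeded the 95th percentile of the SDs of another organism's probe sets. An alternative for paralogs beyond leaving out probe sets of several genes could not be had.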

Other observations

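Tests chosen after the result was seen are all those of this part except the list tests of zinc, phosphate, iron, meiosis and mating-type genes.

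Metal and phosphate genes differed between the cultures. Of 16 zinc-regulated genes 8 rose and 1 fell in immobilized against log-phase cells (8 and 1 adjusted over the list alone), with URA10 at 2.36 ± 0.40 and IZH2 at 2.23 ± 0.17, adjusted p = 0.00578, and adjusted p = 0.267 with an estimated correlation. Of 17 phosphate starvation genes 5 rose against the chemostat (5 adjusted over the list alone), led by the phosphate transporter gene PHO84 at 4.46 ± 0.78 and GIT1 at 2.74 ± 0.56, with adjusted p = 0.0182, and adjusted p = 0.495 with an estimated correlation. Of 29 iron regulon genes 15 were lower and 1 higher in immobilized than in stationary-phase cells (15 and 1 adjusted over the list alone), with FIT2 at -4.37 ± 0.45 and the siderophore transporter gene SIT1 at -2.64 ± 0.30, adjusted p = 0.000372, and adjusted p = 0.731 with an estimated correlation.

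In the anaerobic list the 11 DAN, TIR and PAU genes had a median of 2.17 in immobilized against log-phase cells, with 8 called higher, and the other 17 genes 0.56, with 7 higher and 3 lower. Against stationary phase the medians were 4.17 and 1.14, and against the chemostat 2.15 and 0.34. Between stationary and log phase they were -0.21 and -0.58. The difference between the 2 parts was not tested. Some PAU probe sets can bind several PAU genes, so the 11 are not independent measurements. DAN1 is not among the 11, because it had no value at day 0. Its mean log2 ratio was -0.20 in log phase, against 0.09, -0.03, 0.15, 0.16 and 0.35 at days 1, 3, 5, 10 and 17. DAN1 thus hardly rose over log phase, while it was lower in stationary phase (-4.77) and the chemostat (-1.94).

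The 4 genes with missing values were not tested. SPG1 had no value in log phase and ratios of 1.41 to 1.56 in stationary phase, 0.0995 to 0.122 in the chemostat and 0.0627 to 1.15 at day 1. SPS100 had none in log phase either and ratios of 0.387 to 0.425 in the chemostat. NCA3 had none in stationary phase, 0.012 in the 1 log-phase array with a value, 0.13 to 0.194 at day 0 and 0.441 to 1.34 at day 1. DAN1, an anaerobic cell wall gene, had none at day 0, 0.827 to 0.912 in log phase, 0.031 to 0.0434 in stationary phase and 0.742 to 1.54 at day 1.

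In immobilized against log-phase cells the 4 alpha-specific genes fell (4 adjusted over the list alone), with a median of -2.65, STE3 at -2.78 ± 0.40, adjusted p = 0.0026, and adjusted p = 0.281 with an estimated correlation. Of 23 meiosis and sporulation genes 13 rose and 1 fell (13 and 1 adjusted over the list alone), with SPR28 at 3.60 ± 0.62 and SPO74 at 2.93 ± 0.74, adjusted p = 0.000268, and adjusted p = 0.374 with an estimated correlation; the alpha-factor gene MF(ALPHA)1 and SPO74 lost the call with repeated quantile normalization. Both are features of cells that express both mating types, and a haploid strain of mating type alpha was used. Of the 7 a-specific genes 1 was called higher, with a median of 0.38, which argues against an admixture of cells of mating type a as the whole cause. Their median was 1.13 in stationary phase, 0.55 in the chemostat and 1.94 at day 0, all against log phase. The median of 11 haploid-specific genes was -0.654, with 0 higher and 5 lower (GPA1, FUS3, FAR1, HO and SST2). The others were not called: STE4 at -0.65, NEJ1 at -0.35, AXL1 at -0.25, STE18 at -0.005, RME1 at 0.28 and STE5 at 0.50. The genes thus did not move together. Their median lay between the bounds set for and against expression of both mating types, so that this stayed open. The alpha-specific genes also fell in stationary phase (median -2.27), at day 0 (-2.94) and in the chemostat (-2.04). A fall of these genes whenever growth slows may therefore account for their part of the pattern. All these medians share the same 2 log-phase arrays, in which the list averaged 2.16 and 3.1. High values in those arrays alone would also give a fall in each comparison. The sporulation list averaged -1.03 in log phase, -0.959 in the chemostat, -0.233 in stationary phase and -0.0111 at day 0. In immobilized cells it differed by day, with -0.436 at day 1 (arrays from -1.18 to 0.67), 0.0692 at day 3 and 0.382 at day 5. At days 10 and 17 it was 1.04 and 0.465. At day 0 against log phase 9 of the 23 rose and 1 fell (9 and 1 adjusted over the list alone), with adjusted p = 0.00604, and adjusted p = 0.495 with an estimated correlation. In stationary phase 4 rose (2 adjusted over the list alone) and the list was not called (adjusted p = 0.0916).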
